A study of Arabidopsis thaliana with 12 samples.

How the data were processed

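Messenger RNA and N6-methyladenosine (m6A) were measured in Arabidopsis thaliana Col-0 wild type and in a dcl1 mutant. DCL1 encodes the Dicer-like enzyme that cuts microRNAs out of their primary transcripts. Per the labels' protocols, poly(A) RNA was selected with oligo(dT) beads and fragmented, and part of it was immunoprecipitated with an m6A antibody. Libraries were then made from the immunoprecipitate (MeRIP-seq) and from the input fraction (RNA-seq), and were sequenced as paired ends. Each genotype had 3 replicates of each kind of library, 12 libraries in all, and the series design states that the replicates were biological. The labels give an age of 20 days and a leaf source, whereas the protocol and the series design speak of seedlings and of a 3-week stage. They do not name the dcl1 allele.

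Per the submitters' processing notes, fastp, HISAT2, StringTie, edgeR, HOMER and ChIPseeker were used with the TAIR10 build. The notes give neither their versions nor what each was used for. The expression table deposited by the authors holds FPKM (fragments scaled by gene length and library total) of 24730 genes in the 6 input libraries, per the file headers. The authors' expression comparison holds, per the file headers, a fold ratio of mean FPKM in dcl1 over wild type, its log2, a p-value and a q-value. Recomputed from the FPKM columns, that ratio was found to carry no pseudocount, and the genes the authors marked as significant had a p-value under 0.05 and at least a 2-fold change. The peak table deposited by the authors holds 3117 differential m6A peaks. Each has a log2 change of dcl1 over wild type, a p-value, the log10 of its FDR, a region of the transcript and an assigned gene, per the file headers. How that log2 change was scaled, and whether it was taken relative to input, is not stated. Every peak in that table had a p-value under 0.05 (largest 0.049), so peaks that did not differ were not part of it. Values of single immunoprecipitate libraries were not used here. FPKM give no sequencing depth, so the depth is unknown and no counting intervals or detection floors are given.

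Gene symbols came from a RefSeq table of assembly TAIR10.1, used for names alone. Of the 24730 gene identifiers, 23755 matched a locus tag exactly and 24354 did after a transcript suffix was removed, and 9808 had a symbol other than the locus. Genes of the fixed lists that have no symbol there (HTT1, HIZ1, HIZ2, SPL6 and the ALKBH genes among those named) carry the name of the list with their locus. Coordinates are 1-based, as the authors' tables give them on TAIR10.

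Expression was compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend) on log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 6 input libraries were tested, two-sided, with Benjamini-Hochberg adjustment and an adjusted p-value threshold of 0.05. The pseudocount of 1 FPKM makes fold changes of genes with low FPKM smaller than the ratio of their means. The test was tried on simulated data for the comparison of dcl1 with wild type. Among 17925 simulated genes it recovered 100% of 100 genes changed 2-fold and 99% of 100 genes changed 4-fold, and 5.69% of its calls were false. The changed genes were drawn only from those averaging above about 5 FPKM, with independent normal noise and no shift of a whole library. Recovery at lower expression, or with as many changed genes as the data gave, was not simulated. The tested genes include families of close paralogs and overlapping or antisense neighbours. How reads shared between them were counted, and whether counting followed the strand, is not stated.

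Gene lists were fixed before the data were examined, as were the tests and the rule for named genes. They cover miRNA targets, targets and precursors of trans-acting siRNAs, small RNA machinery, m6A machinery, photosynthesis, salicylic acid defence, jasmonate, ABA with cold and drought, flowering and floral genes, cell cycle, flavonoid synthesis, auxin response, phosphate starvation, senescence, and markers of root, seed and meristem. The list of MIR genes is every tested gene with a MIR symbol. Lists with at least 3 tested genes were compared with the other genes by camera with a preset correlation of 0.01, adjusted over 18 lists. Each list test was repeated with an estimated correlation and with fry. The p-value of fry tests whether a list's genes move on balance in one direction, and does not compare the list with other genes. Gene Ontology terms of 10 to 500 tested genes, as annotated in the authors' table, were tested with camera after the list results had been seen.

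The named genes were DCL1, the 5 largest rises and 5 largest falls among called genes with a symbol, non-overlapping groups and at least 5 FPKM in the higher group, and up to 3 rises and 3 falls per list among called genes with non-overlapping groups. Where a list had none, its largest change was named. The named peaks were the 5 largest gains and 5 largest losses in genes with a symbol and at least 5 FPKM, and up to 3 peaks per list with the largest absolute change. Peaks were named by the 1 gene of the expression table whose coordinates they overlap, because the authors' assignment often gave a neighbouring gene. That choice was made after the peak table was seen.

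Peak directions were counted once per gene and compared by an exact two-sided binomial test with a Clopper-Pearson 95% interval, in scipy 1.17.1 under Python 3.11.15. Peak location, and m6A direction against expression direction, were compared by two-sided Fisher exact tests. Spearman correlations across peaks used 100000 permutations, and peaks and genes are not independent replicates. The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, median-ratio and quantile scaling, no variance trend, array weights, a replicate block, the authors' calls, stricter peak thresholds, and leaving out each input library in turn. The replicate numbers were checked for pairing as the correlation across genes of the deviations from the genotype means. For libraries of the same number it was 0.0850, 0.0608 and 0.150, not above 0.1 for every number, so the block entered as an alternative alone.

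The planned test of m6A enrichment per library, the motif test and the re-annotation of peaks from a reference genome were not run. The first needs values of single immunoprecipitate libraries, which were not used here, and the others need a genome sequence or gene models, which were not used here.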

Results

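RNA-seq of input RNA and m6A MeRIP-seq were performed on wild type (Col-0) and a dcl1 mutant, with 3 biological replicates per genotype and assay. The material is leaf by the labels and seedlings by the protocol and the series design. The sum of FPKM over all genes lay between 616106 in dcl1 replicate 2 and 622995 in wild-type replicate 2. Between 17453 and 17908 genes exceeded 1 FPKM in a library. Across tested genes, libraries of 1 genotype correlated at r = 0.985 to 0.993 and libraries of different genotypes at r = 0.925 to 0.959. The first principal component held 78.2% of the variance and parted the genotypes. On it, wild-type replicate 3 (-26.1) lay nearer to dcl1 than wild-type replicates 1 (-41.1) and 2 (-42.8). Genes of the chloroplast genome made up 0.774% of all FPKM in dcl1 replicate 1 and from 0.0925% to 0.192% in the other libraries. Those of the mitochondrial genome made up from 0.0202% to 0.0395% in dcl1 and from 0.00951% to 0.0110% in wild type.

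The first comparison asked which transcripts differ in level when DCL1 is impaired. DCL1 itself (AT1G01040, chromosome 1, 23146 to 31227) was low in every mutant library. Its FPKM was 5.08, 4.53 and 6.0 in wild-type replicates 1, 2 and 3, and 0.604, 0.406 and 0.632 in dcl1 replicates 1, 2 and 3. The means were 5.20 ± 0.739 and 0.547 ± 0.124 (SD, n = 3 each), 9.51-fold lower in the mutant (log2 -2.0, SE 0.12, limma adjusted p = 1.1e-04). Of 17925 genes tested, 5480 changed, 3189 upward and 2291 downward. At least 2-fold changes were found for 749 risen and 219 fallen genes, 968 in all. This number depends on the pseudocount, and was 1308 with 0.1 FPKM and 506 with 5 FPKM. In 5457 of the 5480 genes the libraries of the genotypes did not overlap; this held for 48.4% of all tested genes, where chance gives 10%. The count fell to 3226 without wild-type replicate 1 and to 3205 without wild-type replicate 2, and was 5663 without wild-type replicate 3. Rises made up 58.2% of the calls with FPKM as deposited and 40.0% of 6197 calls after quantile normalization, so the balance of directions turned with the scaling.

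Among called genes with a symbol, at least 5 FPKM in the higher genotype and libraries of the genotypes that did not overlap, the 5 largest rises and the 5 largest falls were as follows. MIR398b (AT5G14545), whose microRNA targets copper/zinc superoxide dismutases, went from 0.352 ± 0.158 to 122 ± 17.9 FPKM (log2 6.51, SE 0.13, adjusted p = 8.9e-07). RRTF1 (AT4G34410), a redox-responsive transcription factor, went from 0.986 ± 0.748 to 94.0 ± 33.2 FPKM (log2 5.58, SE 0.32, adjusted p = 8.1e-05). MIR172b (AT5G04275) rose by 5.35 on the log2 scale. ORA47 (AT1G74930), a regulator of jasmonate synthesis, rose by 5.32, and MIR319a (AT4G23713) by 5.23. PRE1 (AT5G39860), a helix-loop-helix protein that promotes cell elongation, dropped from 21.9 ± 6.61 to 0.618 ± 0.153 FPKM (log2 -3.78, SE 0.22, adjusted p = 8.1e-05). XTH7 (AT4G37800), a xyloglucan endotransglucosylase, dropped from 193 ± 13.9 to 26.1 ± 6.34 FPKM (log2 -2.87). SNZ (AT2G39250), an AP2-like repressor of flowering targeted by miR172, changed by -2.78. HFR1 (AT1G02340), a far-red light signalling factor, changed by -2.76. YUC9 (AT1G04180), an auxin synthesis enzyme, changed by -2.62 (SE 0.52, adjusted p = 0.0096). Its FPKM was 11.2, 8.19 and 1.54 in wild-type replicates 1, 2 and 3, and was listed at 0 in dcl1 replicate 3.

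The tested MIR genes, loci of microRNA primary transcripts, rose as a group. Of 129 in the table, 52 were tested, of which 45 rose and 2 fell (46 and 2 adjusted over the list alone), with a median log2 change of 2.11 (camera adjusted p = 2.4e-24). This call held with an estimated correlation (adjusted p = 0.0038 with an estimated correlation), as did no other list. MIR398b, MIR172b and MIR319a changed most. MIR775 (AT1G78206, log2 -0.78, adjusted p = 0.023) and MIR414 (AT1G67195, log2 -0.70, adjusted p = 0.0024) fell. The MIR775 call was lost without wild-type replicate 1 (adjusted p = 0.0757) or wild-type replicate 2 (adjusted p = 0.079). Of the 52 loci, 38 were shorter than 200 bases, which makes their FPKM imprecise, and 8 overlapped another gene. Among the other 44, 39 rose and 2 fell, with a median of 2.47. The minimum of 1 FPKM was a mean over both genotypes, so loci near 0 in wild type were tested only if high in dcl1. Of 40 MIR genes that rose at least 2-fold, 8 had a wild-type mean of at least 1 FPKM. This selection favours rises, so the share that rose, the medians and the list test reflect it in part.

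**Figure D1:**
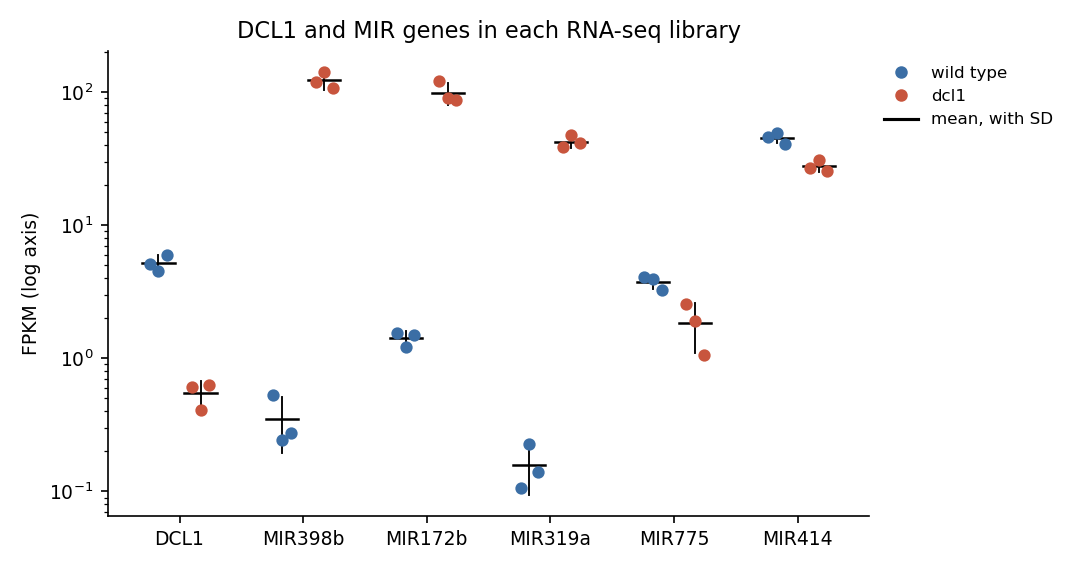
FPKM of DCL1 and of the MIR genes with the largest changes in each RNA-seq library, on a log axis; points are libraries, horizontal bars are means and vertical bars are SD (3 libraries per genotype). DCL1 averaged 5.20 FPKM in wild type and 0.547 in dcl1, and MIR398b 0.352 and 122.

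Established miRNA targets were higher in dcl1. Of 80 tested, 42 rose and 4 fell (45 and 4 adjusted over the list alone), with a median log2 change of 0.38 (camera adjusted p = 8.3e-08; adjusted p = 0.41 with an estimated correlation). The largest rises were in NF-YA2 (AT3G05690, 2.42), NF-YA3 (AT1G72830, 1.86) and NF-YA5 (AT1G54160, 1.54), subunits of the CCAAT-box factor targeted by miR169. SNZ (-2.78), DCL1 (-2.0), whose transcript is the target of miR162, and SMZ (AT3G54990, -1.29), another AP2-like miR172 target, fell. Of 6 tested targets of trans-acting siRNAs, 5 rose and 0 fell, the same counts adjusted over the list alone, with a median of 0.54 (adjusted p = 0.024; adjusted p = 0.41 with an estimated correlation). That call was lost without wild-type replicate 3 (adjusted p = 0.0535), dcl1 replicate 2 (0.103) or dcl1 replicate 3 (0.0525), and with genes of at least 5 FPKM alone (0.113). HTT1 (AT4G29770) rose by 0.94, the auxin response factor ETT (AT2G33860) by 0.74 and RPF2 (AT1G62670) by 0.58. The HTT1 call was lost without wild-type replicate 1 (0.053), and that of RPF2 without wild-type replicate 2 (0.056), dcl1 replicate 1 (0.0662) or dcl1 replicate 3 (0.0584). Among 5 precursors of these siRNAs, TAS1C (AT2G39675) rose from 13.1 ± 0.772 to 32.6 ± 0.992 FPKM (log2 1.25) and TAS2 (AT2G39681) by 0.30, and 0 fell, also adjusted over the list alone. The precursor list had a median of 0.22 and did not pass (adjusted p = 0.17; adjusted p = 0.51 with an estimated correlation).

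In the small RNA machinery, 7 of 26 genes rose and 2 fell, also adjusted over the list alone, and the list did not pass (median 0.12, adjusted p = 0.29). AGO2 (AT1G31280), an argonaute targeted by miR403, rose by 0.75 on the log2 scale, HYL1 (AT1G09700), the partner of DCL1 in processing, by 0.48, and SGS3 (AT5G23570), needed for trans-acting siRNAs, by 0.37. Besides DCL1, AGO7 (AT1G69440), the argonaute of miR390, fell (-0.33, adjusted p = 0.040). Its call was lost with any 1 of the 6 libraries left out (adjusted p from 0.0551 without dcl1 replicate 2 to 0.111 without dcl1 replicate 3). In the m6A machinery, 2 of 24 genes rose and 3 fell, and 0 rose and 3 fell adjusted over the list alone (median -0.06, adjusted p = 0.34). The putative writer component HIZ1 (AT1G32360) rose by 0.38 and the YTH-domain gene ECT9 (AT1G27960) by 0.31. ALKBH10B (AT4G02940), an m6A demethylase, changed by -0.46 (adjusted p = 0.013), ALKBH9C (AT4G36090), of the same family, by -0.40 and ECT7 (AT1G48110) by -0.30. The ALKBH10B call was lost without wild-type replicate 1 (adjusted p = 0.0513). The ECT7 call was lost without wild-type replicate 1 or 2 or dcl1 replicate 2 or 3 (0.0573 to 0.0893), and the HIZ1 call with any library but wild-type replicate 3 left out (0.0635 to 0.114). The ECT9 call was lost with any library but wild-type replicate 1 left out (0.0894 to 0.13) and after quantile (0.12) or median-ratio scaling (0.0515).

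Jasmonate genes rose in dcl1. Of 25 tested, 21 rose and 0 fell, also adjusted over the list alone, with a median log2 change of 1.18 (camera adjusted p = 4.7e-08; adjusted p = 0.50 with an estimated correlation). AOC3 (AT3G25780), an allene oxide cyclase of jasmonate synthesis, went from 7.25 ± 3.22 to 74.1 ± 22.3 FPKM (log2 3.21), and the JAZ repressors JAZ5 (AT1G17380) and JAZ8 (AT1G30135) rose by 3.18 and 3.06. Of 24 ABA, cold and drought genes, 11 rose and 4 fell (14 and 5 adjusted over the list alone), with a median of 0.71 (adjusted p = 0.010; adjusted p = 0.41 with an estimated correlation). The cold regulators CBF2 (AT4G25470) and CBF1 (AT4G25490), neighbouring paralogs, rose by 3.51 and 2.66, and the cold-induced COR15B (AT2G42530) by 2.54. GolS3 (AT1G09350, -1.05), LTI78 (AT5G52310, also RD29A, -0.78) and the phosphatase ABI2 (AT5G57050, -0.35) fell. The ABI2 call was lost without wild-type replicate 1 (0.0672), dcl1 replicate 2 (0.0535) or dcl1 replicate 3 (0.052).

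Salicylic acid defence genes did not pass as a list. Of 17 tested, 5 rose and 0 fell (5 and 1 adjusted over the list alone), with a median log2 change of 0.0975 (camera adjusted p = 0.40). After quantile normalization the median was -0.00728 (camera adjusted p = 0.25). The regulator CBP60G (AT5G26920) rose by 2.03, PBS3 (AT5G13320) by 1.33 and WRKY70 (AT3G56400) by 1.05. The WRKY70 call was lost without wild-type replicate 1 or 2 or dcl1 replicate 2 or 3 (0.0819 to 0.0898). Of 13 senescence genes, 5 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.36, adjusted p = 0.24). WRKY53 (AT4G23810) rose by 1.6, NAC6 (AT5G39610) by 1.25 and SAG21 (AT4G02380) by 1.23, and ACD1 (AT3G44880), an enzyme of chlorophyll breakdown, changed by -0.33. The NAC6 call was lost without wild-type replicate 1 (0.0591), dcl1 replicate 2 (0.0542) or dcl1 replicate 3 (0.064). The ACD1 call was lost without wild-type replicate 1 or 2 or dcl1 replicate 1 or 2 (0.105 to 0.132). Wild-type replicate 3 moved with several of these lists. Relative to wild-type replicates 1 and 2, its list median was 0.75 for salicylic acid defence, 0.29 for jasmonate, 0.16 for senescence and 0.13 for ABA, cold and drought. In the dcl1 libraries these medians lay between 0.20 and 0.56, 0.76 and 1.54, 0.20 and 0.90, and 0.39 and 0.93. For MIR genes, wild-type replicate 3 stood at 0 and dcl1 between 2.06 and 2.09. Most MIR genes that rose at least 2-fold averaged under 1 FPKM in wild type, so this 0 says little about a shift there.

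**Figure D2:**
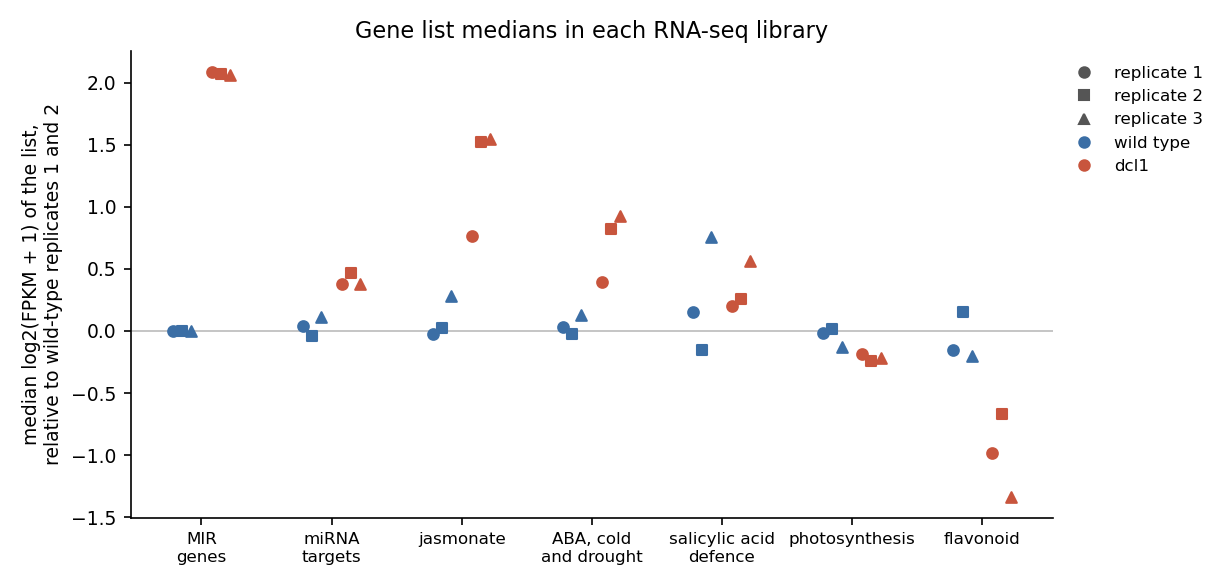
Median log2(FPKM + 1) of the tested members of 7 gene lists in each RNA-seq library, relative to wild-type replicates 1 and 2; blue is wild type, red is dcl1, and symbols mark the replicate. MIR genes stood between 2.06 and 2.09 in dcl1 and at 0 in wild-type replicate 3, and salicylic acid defence at 0.75 in wild-type replicate 3. Most MIR genes that rose at least 2-fold averaged under 1 FPKM in wild type.

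Flavonoid and anthocyanin genes were lower in dcl1. Of 12 tested, 0 rose and 9 fell (0 and 11 adjusted over the list alone), with a median log2 change of -0.93 (camera adjusted p = 1.1e-05; adjusted p = 0.50 with an estimated correlation). LDOX (AT4G22880, anthocyanidin synthase) changed by -1.46, TT4 (AT5G13930, chalcone synthase) by -1.29, from 154 ± 20.7 to 65.9 ± 28.0 FPKM, and TT7 (AT5G07990, flavonoid 3'-hydroxylase) by -1.27. Without wild-type replicate 2 all 3 calls were lost (adjusted p = 0.0527, 0.0562 and 0.0699). Of 45 photosynthesis genes, 3 rose and 17 fell (3 and 18 adjusted over the list alone), with a median of -0.19 (adjusted p = 6.0e-04; adjusted p = 0.64 with an estimated correlation). After quantile normalization that median was -0.0125 and the call was lost (adjusted p = 0.57). LHCB4.3 (AT2G40100, -1.22), RBCS1B (AT5G38430, a Rubisco small subunit with close paralogs, -0.83) and PSBQA (AT4G21280, -0.64) fell. The light-harvesting genes CAB3 (AT1G29910, 0.37), CAB1 (AT1G29930, 0.36) and LHCB4.2 (AT3G08940, 0.29) rose. CAB1 and CAB3 are paralogs whose reads can be shared. The CAB3 call was lost without wild-type replicate 1 (0.0703) or 3 (0.0549) or dcl1 replicate 1 (0.0541) and with median-ratio scaling (0.0574). The CAB1 call was lost without wild-type replicate 1 (0.0535) and after quantile normalization (0.353). In wild-type replicate 3 the medians relative to replicates 1 and 2 were -0.20 for flavonoid and -0.13 for photosynthesis genes.

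Auxin response genes moved in both directions. Of 10 tested, 2 rose and 4 fell, also adjusted over the list alone (median log2 change -0.12, adjusted p = 0.25). IAA29 (AT4G32280, -2.05), IAA5 (AT1G15580, -1.62) and SHY2 (AT1G04240, also IAA3, -1.25), early auxin-induced repressors, fell. The auxin-conjugating enzymes WES1 (AT4G27260, also GH3.5) and GH3.3 (AT2G23170) rose by 0.98 and 0.50. The GH3.3 call was lost without wild-type replicate 2 (0.0628), dcl1 replicate 1 (0.0543) or dcl1 replicate 2 (0.0626). Of 21 cell cycle genes, 1 rose and 4 fell (1 and 3 adjusted over the list alone), with a median of -0.20 (adjusted p = 0.033; adjusted p = 0.64 with an estimated correlation). That call was lost without wild-type replicate 1 (0.102) or 3 (0.0828), dcl1 replicate 1 (0.123) or 2 (0.0801), and with genes of at least 5 FPKM alone (0.252). The B-type cyclin CYCB1;3 (AT3G11520, -0.56), CDC20.1 (AT4G33270, -0.46) and the kinase AUR2 (AT2G25880, -0.44) fell, and the D-type cyclin CYCD3;1 (AT4G34160) rose by 0.54. The CDC20.1 call was lost without wild-type replicate 1 (0.0671), dcl1 replicate 1 (0.0559) or dcl1 replicate 2 (0.0564). The AUR2 call was lost without wild-type replicate 1 or 3 or dcl1 replicate 1 or 2 (0.0597 to 0.097).

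Flowering and floral genes included both repressors and promoters of flowering among those that moved. Of 11 tested, 7 rose and 2 fell (7 and 3 adjusted over the list alone; median 0.53, adjusted p = 0.12). After quantile normalization the list passed (adjusted p = 0.047). FLC (AT5G10140), a repressor of flowering, went from 1.33 ± 0.351 to 10.8 ± 2.61 FPKM (log2 2.33). AP1 (AT1G69120) and AGL8 (AT5G60910, also FUL), which promote floral fate, rose by 0.81 and 0.73. SEP1 (AT5G15800, -1.07) and AGL24 (AT4G24540, -0.39) fell. The AGL24 call was lost with any library but dcl1 replicate 2 left out (0.0604 to 0.111). Of 5 meristem markers, 2 rose and 0 fell (3 and 0 adjusted over the list alone; median 0.34, adjusted p = 0.25). KNAT6 (AT1G23380) rose by 0.38 and STM (AT1G62360) by 0.34. The KNAT6 call was lost without wild-type replicate 1 or 2 or dcl1 replicate 2 or 3 (0.0615 to 0.0702). The STM call was lost with any library but wild-type replicate 3 left out (0.0668 to 0.12), and after quantile normalization (0.0785), and its change was 0.22 without wild-type replicate 2. Only 3 of 17 root markers were tested, and they had a median of -0.02 but a mean of 0.27 (camera direction up, adjusted p = 0.97). Over the 6 input libraries, IRT1 (0.193 FPKM), CASP1 (0.27) and PLT2 (0.00455) averaged near 0, whereas SHR (9.39) and PHO1 (7.43) did not. With most root markers under the minimum or not listed, the libraries gave little sign of root. NRT2:1 (AT1G08090), a nitrate transporter, rose by 1.06, also adjusted over the list alone, a call lost with wild-type replicate 1 or 2 or dcl1 replicate 1 or 3 left out (0.0685 to 0.0913). Of 13 seed markers, 8 were in the table and 0 reached the expression minimum, so limma tested none. Of 7 phosphate starvation genes, 0 passed in limma, also adjusted over the list alone (median -0.08, adjusted p = 0.34). SPX1 (AT5G20150) had the largest change among them (-0.45, adjusted p = 0.42), and passed without wild-type replicate 3 (-0.98, adjusted p = 0.0012).

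**Figure D3:**
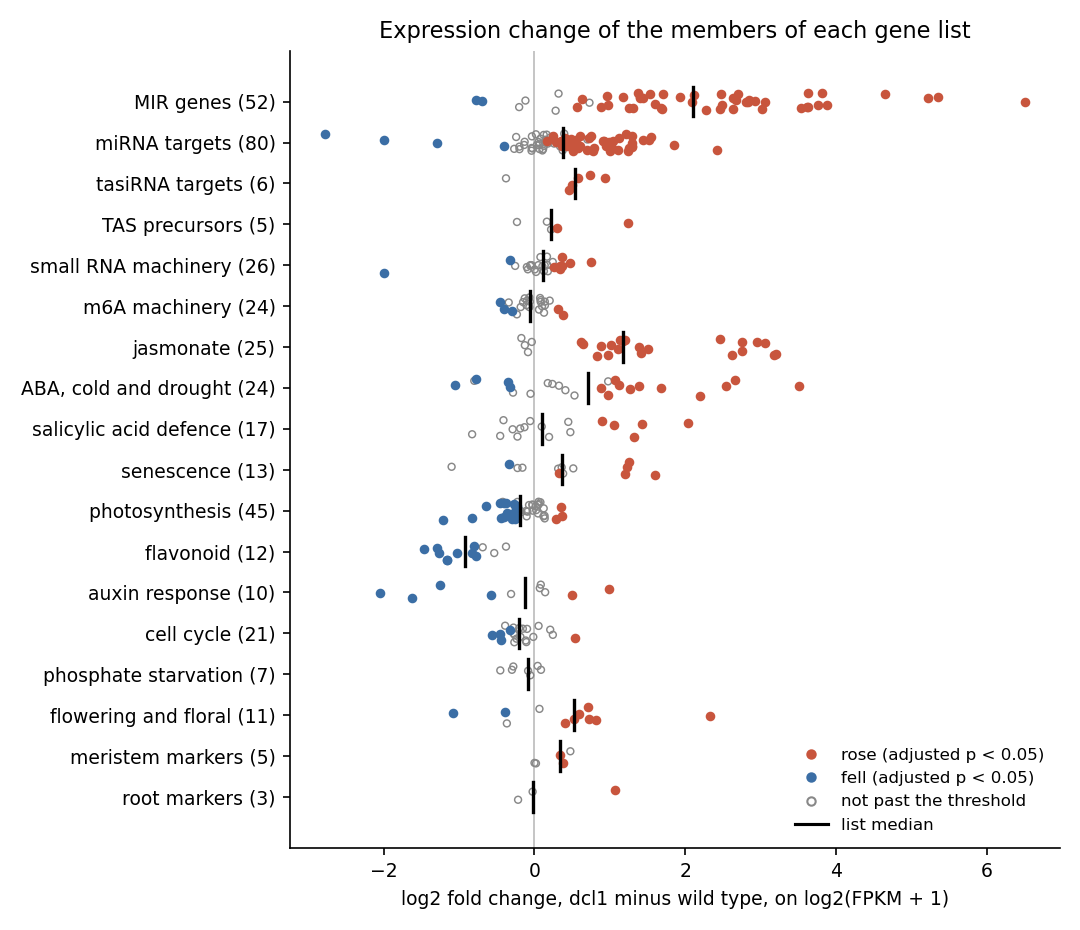
Log2 change of dcl1 against wild type for each tested member of 18 gene lists (number of members in parentheses); filled points passed an adjusted p of 0.05 and bars are list medians. MIR genes had a median of 2.11, jasmonate genes of 1.18 and flavonoid genes of -0.93.

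The authors' own comparison marked 1669 genes as significant, 1172 higher and 497 lower in dcl1. Of these, 1398 were among the genes tested here, and 1317 passed the limma threshold in the same direction. At a q-value under 0.05 the authors' table held 5493 genes, and 4598 of them passed in the same direction.

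The second comparison asked which transcripts carry more or less m6A in dcl1. Of 3117 differential peaks called by the authors, 1879 were higher and 1238 lower in dcl1. Changes were mostly small, with medians of 0.289 among higher and -0.31 among lower peaks on the log2 scale, and 46 higher and 80 lower peaks changed at least 2-fold. By the authors' assignment of peaks to genes, 1781 genes had higher and 1168 lower peaks, and 40 had both. Many of these peaks do not overlap the assigned gene. Counted by the 1 gene each peak overlaps, 1488 genes had higher and 1042 lower peaks, and 8 had both (58.8% higher). By the assigned gene, higher peaks made up 60.4% of genes with 1 direction (95% interval 58.6 to 62.2, exact binomial p = 1.2e-29). Genes are not independent trials, so the binomial intervals and p-values here do not measure variation between libraries. How the peak changes were scaled is not stated, and an offset of scale could move this balance. Among changes of at least 2-fold the balance turned, with higher peaks in 46 and lower peaks in 78 genes (37.1%, 28.6 to 46.2, exact p = 0.0052). The FDR exceeded 0.05 for 636 peaks.

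By the authors' annotation, most peaks lay in the 3' UTR. Of the higher peaks, 1781 (94.8%) lay there, and of the lower peaks 1125 (90.9%; Fisher exact adjusted p = 4.5e-05). Exons outside the UTRs held 81 higher (4.31%) and 105 lower peaks (8.48%; adjusted p = 6.3e-06). The 5' UTR held 17 higher (0.905%) and 8 lower peaks (0.646%; adjusted p = 0.54). Among peaks changed at least 2-fold, the 3' UTR share was 65.2% of higher and 80% of lower peaks (adjusted p = 0.13). Of 2975 peaks whose assigned gene was in the expression table, 1175 did not overlap it. Among 156 exon peaks that overlapped 1 gene, the annotation named that gene for 152.

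Peaks were ranked among those that overlapped 1 gene alone, with a symbol and at least 5 FPKM. The largest gains of m6A among them were in SAP130a (AT3G55200, chromosome 3, 20463958 to 20464556, log2 1.95), a predicted splicing factor subunit, and in 4CL3 (AT1G65060, 1.1), an enzyme of phenylpropanoid synthesis. ARR7 (AT1G19050, 1.02), a cytokinin response regulator, TOM22-I (AT1G04070, 1.01), of the mitochondrial import complex, and NIP5;1 (AT4G10380, 1.00), a boric acid channel, followed. Under the same limits, the largest losses were in NAC062 (AT3G49530, chromosome 3, 18362472 to 18362738, -2.20), a membrane-bound stress transcription factor, and in S6K2 (AT3G08720, -1.76), a ribosomal protein kinase. Losses followed in ERD7 (AT2G17840, -1.63), RABH1c (AT4G39890, -1.52) and TIP (AT5G24590, -1.44). All 10 peaks were annotated to the 3' UTR. Transcripts of all 5 genes with these losses rose, by 2.56, 1.99, 2.1, 1.1 and 2.32 in the same order. Of the 5 with gains, 4CL3 (-1.14) and ARR7 (-1.28) fell in expression, NIP5;1 rose by 0.48, and SAP130a and TOM22-I did not pass. A peak at the 3' end of DCL1 (chromosome 1, 30692 to 31227) was lower in dcl1 by -1.63, and the authors assigned it to the embedded MIR838a. DCL1 averaged 0.547 FPKM in dcl1, so that change rests on little RNA in the mutant. Another peak, from 31169 to 31770, changed by -0.44. It was assigned to the neighbouring AT1G01050 and lies mostly beyond the end of DCL1 at 31227.

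Within the lists, differential peaks that overlapped 1 gene alone were few. The 547 peaks over 2 genes and the 5 over 3 genes were not counted here, among them the DCL1 peak of -1.63. DCL1 is in the lists of miRNA targets and of small RNA machinery. Among miRNA targets 11 genes had 8 higher and 3 lower peaks, the largest in ARPN (0.72), SPL6 (-0.70) and AGO2 (-0.60). Targets of trans-acting siRNAs had them in ARF2 (-0.42) and ARF4 (0.30). The small RNA machinery had 1 higher and 4 lower peaks, including HST (0.33) and RDR6 (-0.29, FDR 0.12) besides AGO2. In the m6A machinery 3 peaks were higher and 3 lower, the largest in ECT8 (0.71), HIZ2 (-0.43) and EMB2016 (0.35), the writer subunit also known as VIRILIZER. Photosynthesis genes had 6 higher and 0 lower peaks in 5 genes, led by LHCB4.3 (0.79), LHCA1 (0.40) and LHCA2 (0.32). Jasmonate genes had 0 higher and 3 lower peaks, in JAZ6 (-0.60), TIFY10B (-0.53, also JAZ2) and JAR1 (-0.33). ABA, cold and drought genes had peaks in P5CS1 (-0.48) and ABF3 (0.20), and senescence genes in NYE1 (-0.48) and ACD1 (0.36). Single peaks lay in EDS16 of salicylic acid synthesis (0.40), SEP3 (0.90), AUR2 (0.44), SQD2 (-0.26), STM (0.24) and MIR824 (0.90). The lists of siRNA precursors, flavonoid, auxin, root and seed genes had 0 differential peaks that overlapped 1 gene alone. The authors' table holds only peaks with an unadjusted p under 0.05. These counts were not tested for enrichment.

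The third comparison asked whether m6A and transcript level changed in the same or in opposite directions. Peaks and expression mostly moved in opposite directions. By the authors' assignment of peaks, 801 genes had peaks in 1 direction and a called expression change. Of these, 462 had higher m6A, and the transcript fell in 310 of them (67.1%). Lower m6A was found in 339, and the transcript rose in 281 of them (82.9%). The log2 odds ratio of the same over opposite directions was -3.30 (95% interval -3.80 to -2.81, Fisher exact p = 3.8e-47). Without the requirement of a called expression change, over 2445 genes, they were -1.56 (-1.80 to -1.31, Fisher exact p = 9.0e-37). There the transcript was lower for 58.1% of genes with higher m6A, and higher for 68.0% of genes with lower m6A. The number of genes was 465 without wild-type replicate 1, 457 without wild-type replicate 2 and 526 without dcl1 replicate 3, with log2 odds of -3.65, -3.54 and -3.35. With each peak placed in the 1 gene it overlaps, chosen after the table was seen, the log2 odds were -4.83 over 812 genes (Fisher exact p = 1.9e-83). For peaks that did not overlap their assigned gene they were -0.88 over 244 genes (Fisher exact p = 0.021). Across 2514 peaks that overlapped 1 tested gene, Spearman's rho between peak and expression change was -0.412 (permutation p = 1e-05, the smallest that the permutations can give, adjusted p = 1.1e-05 over 9 such relations; Pearson's r = -0.467). Across 871 peaks and the assigned genes they did not overlap, rho was -0.0416 (permutation p = 0.22, adjusted p = 0.22). These are correlations across peaks, which are not independent replicates.

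**Figure D4:**
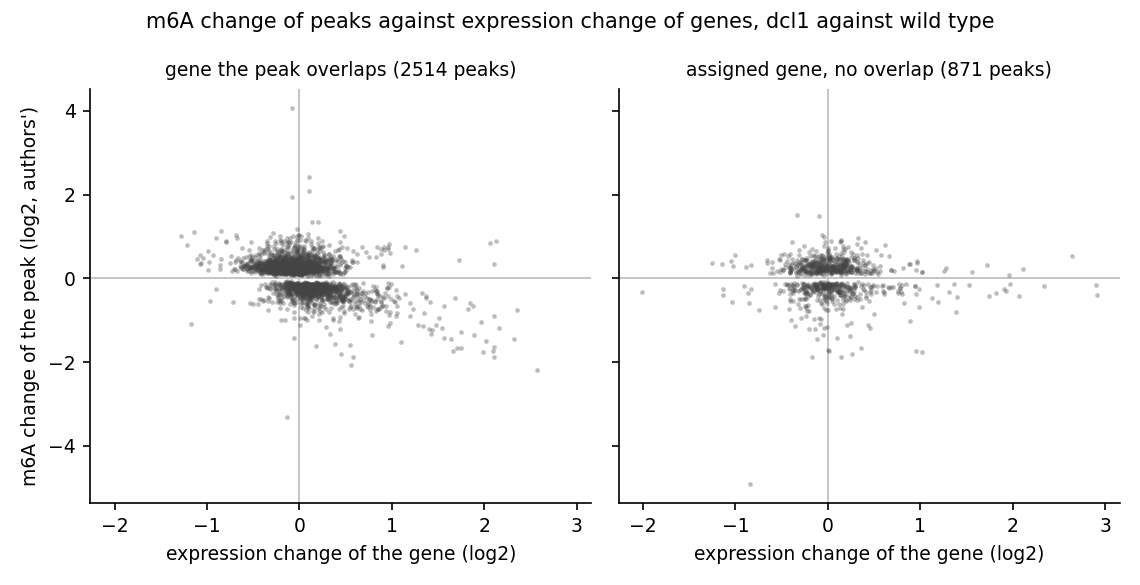
Authors' log2 m6A change of each differential peak against the log2 expression change of a gene, dcl1 against wild type; left, the 1 gene the peak overlaps (2514 peaks), right, the assigned gene where the peak does not overlap it (871 peaks). Spearman's rho was -0.412 on the left and -0.0416 on the right; peaks with changes near 0 are not in the authors' table.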

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

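The alternatives that were added after the data had been seen were the FDR threshold for peaks, both regroupings of peaks by overlap, the rescaled m6A comparisons and the MIR genes free of overlaps. Requiring at least a 2-fold change reduced the 5480 genes to 968, by its own construction, and leaving out 1 library gave 3205 (wild-type replicate 2) to 5663 (wild-type replicate 3), and 3226 without wild-type replicate 1. With an estimated correlation 1 list passed in place of 8. The miRNA targets, with the same median of 0.38, did not (adjusted p = 0.41), and the correlation estimated among their genes was 0.108 against the preset 0.01. With fry, the flavonoid (fry adjusted p = 0.054), photosynthesis (0.093) and cell cycle lists (0.26), called by camera, did not pass. The lists of siRNA precursors (fry adjusted p = 0.0039) and of flowering and floral genes (0.0043), not called by camera, passed with fry. With the replicate number as a block, 5138 genes passed, 8 lists passed in camera and the m6A log2 odds were -3.35. The block ended the calls of AGO7 (limma adjusted p = 0.0725), ECT9 (0.0617), CAB3 (0.0525), AGL24 (0.0523), ACD1 (0.0714) and STM (0.0624). Of 1084 alternative values of 74 named genes, 982 kept direction and call, 101 in 24 genes lost the call, 1 gained it and 0 reversed. Of 306 for the 18 lists, 274 kept both, 20 lost the call, 3 gained it and 9 reversed, all 9 in lists that had not passed. The m6A machinery median was 0.000571 at a minimum of 5 FPKM. The salicylic acid median was -0.0596 with no filter, -0.00728 after quantile normalization, and -0.174 (without wild-type replicate 2) to 0.326 (without wild-type replicate 3) with 1 library left out. The same range was -0.143 (without wild-type replicate 3) to 0.0334 (without wild-type replicate 1) for phosphate starvation and -0.112 (without dcl1 replicate 1) to 0.115 (without dcl1 replicate 3) for root markers; the cause was not tested. Among peaks changed at least 2-fold, 37.1% of genes had higher peaks, and the log2 odds were -1.09 for the 3' UTR (adjusted p = 0.13) and 0.61 for exons (adjusted p = 0.37), the reverse of the values over all peaks; the cause was not tested. The m6A enrichment, motif and re-annotation alternatives were not run. Depth is unknown, so the smallest detectable change of a single gene cannot be given.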

Other observations

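The tests on Gene Ontology terms, on wild-type replicate 3, on the clock genes per library, on the assignment of peaks and on noise among fallen genes were chosen after the result was seen. So were the limits on MIR gene expression, the stricter rules for the clock and for noise, and the genes named here outside the fixed rule. Of 1321 terms, 26 passed upward and 93 downward, and none of those named here held with an estimated correlation (adjusted p = 0.997 for each). Genes of the cellular response to hypoxia rose most clearly, 138 of 209 rising and 5 falling (median log2 change 1.07, camera adjusted p = 8.0e-20). They include RTFL12 (AT4G13395, 5.04), the zinc finger gene RHL41 (AT5G59820, 4.65) and NUDT4 (AT1G18300, 4.47). Genes of the response to chitin rose alongside, 72 of 105 rising and 2 falling (median 1.18, adjusted p = 5.0e-15), among them WRKY40 (AT1G80840, 4.3). Of 177 genes of the response to wounding, 77 rose and 21 fell (median 0.27, adjusted p = 0.0073), with ORA47 and RHL41 among the largest rises. The CCAAT-binding factor complex had 9 of 12 genes rising and 0 falling (median 0.93, adjusted p = 1.1e-05), including NF-YA6 (AT3G14020, 1.46), which is outside the list of miRNA targets.

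Glucosinolate synthesis genes were lower, 17 of 26 falling and 3 rising (median -0.30, adjusted p = 6.9e-04). IPMI2 (AT2G43100, -0.83), BCAT4 (AT3G19710, -0.64) and CYP79F1 (AT1G16410, -0.64), all of the methionine-derived branch, fell. Thylakoid genes fell in 87 and rose in 11 of 216 cases (median -0.17, adjusted p = 1.3e-08). The term shade avoidance did not pass (16 genes, 6 falling and 2 rising, adjusted p = 0.36). Its members HB-2 (AT4G16780, 79.0 ± 13.2 to 16.2 ± 0.625 FPKM, log2 -2.20), PIL1 (AT2G46970, -2.01) and HB4 (AT2G44910, -1.33) fell alongside PRE1, HFR1 and YUC9.

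The real split of the 6 input libraries called 5480 genes and 8 lists, and the highest of the other splits called 0 genes and 7 lists. With 10 splits, of which 1 reached each real value, the share cannot be under 0.1. The limma count at an unadjusted p under 0.05 was 7749 for the real split and at most 646 for the others.

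Many genes that rose at least 2-fold in dcl1 were also higher in wild-type replicate 3 than in wild-type replicates 1 and 2 (84.0% of 749, median log2 shift 0.35), and 219 that fell had a median shift of -0.14 (a median of 16.2% of the way to dcl1, quartiles -22.9% and 44.6%). Some dcl1 RNA in that library would carry MIR transcripts along, yet 27 risen MIR genes of at least 5 FPKM in dcl1 lay a median of -0.0646% of the way to dcl1, against 10.4% for the other risen genes at that level (0% over all 40 risen MIR genes, against 9.88% for the others). A growth or harvest condition that differed between libraries may account for the shift of 0.53 in 96 risen wounding and chitin genes, but this was not decided, as it exceeded 97.4% of random lists matched on expression and 63.6% of those also matched on the size of the rise, and these genes lay 8.56% of the way to dcl1. No such shift was seen in the 8 risen MIR genes with at least 1 FPKM in wild type (median -0.0147, upper quartile 0.13). The rest were near 0 in wild type, where a shift can hardly show. The median of 0 over all 40 therefore does not decide whether such a condition reached them. Which condition differed, and whether it also separates the genotypes, stays open.

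Wounding and chitin genes rose on balance in dcl1, and some shade avoidance genes fell, though the shade term did not pass. Relative to wild-type replicates 1 and 2, the 96 wounding and chitin genes that rose at least 2-fold had medians of 1.92, 2.51 and 2.57 in dcl1 replicates 1, 2 and 3. Their median log2 change between the genotypes, with wild-type replicate 3 included, was 2.15. A different hour of harvest was tested as a cause. Of 10 core clock genes 8 were tested, limma called 0 (1 at an unadjusted p under 0.05), and their median absolute log2 change was 0.23 (median SE 0.24), with 0 changed by 1 or more and the largest in PRR9 (-0.79, adjusted p = 0.081). The bound of 0.5 set beforehand on this change was a poor one, because single dcl1 libraries departed from wild type in opposite directions that cancel in the mean (median absolute departure 0.132, 0.44 and 0.648 in dcl1 replicates 1, 2 and 3, at most 0.135 in wild type). In dcl1 replicate 3 LHY (-1.01) and CCA1 (-0.83) were low and TOC1 (0.71) and ELF3 (0.67) high, while in dcl1 replicate 2 LHY (0.65) was high and GI (-0.77) low. PRR9 did not cancel, as it was low in dcl1 replicates 1, 2 and 3 (-0.72, -1.04 and -0.61) and in wild-type replicate 3 (-0.74). The hour therefore stays open, most of all for dcl1 replicate 3, and an effect of the dcl1 mutation itself or of handling was not told apart from it here.

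Lower m6A on transcripts that rose and higher m6A on transcripts that fell could arise from noise in the input libraries if these entered both measures, and the covariance was -8.29 times the mean squared standard error over 2514 peaks and -1.57 times among 369 peaks in genes that fell. The bound of 2 times set beforehand was too low. The authors' table holds only peaks with an unadjusted p under 0.05, among which noise alone can reach 5.58 times. Over all 2514 peaks the covariance passed that limit but not 2 times it, and among fallen genes it stayed under the limit. Split by expression into sets of 838 peaks, it was -3.86 times in the lowest, -10.1 in the middle and -12.2 in the highest set. The highest set alone passed 2 times the limit, and narrowly. Its covariance was -0.0895 against -0.0962 in the middle set, and its mean squared standard error was smaller (0.00732 against 0.0095). No interval was computed for these ratios, so this argues only weakly against noise alone for the peaks of the highest set. For the other peaks noise stays open. Assignment of peaks to genes they do not overlap is not the source, as rho was -0.416 over the 1728 peaks that overlap their assigned gene. Saturation of the immunoprecipitation stays open too, since rho was -0.340 among genes that fell and -0.463 among genes that rose, which saturation would give. A change of methylation with transcript level, or of transcript level with methylation, would give the same values and was not tested.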
